A study of Mus musculus with 2 samples.

How the data were processed

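Liver RNA from male mice was measured on 2 Affymetrix expression arrays, 1 for a wild-type pool and 1 for a pool labelled as homozygous knockout of Fhl2. Per the labels, each pool combined left-lobe RNA of 3 mice aged 10 to 11 weeks on a mixed Black Swiss/129-SV/J background. The dissected livers were rinsed in cold buffer and frozen, RNA was purified with Trizol and a silica column, and 300 ng of total RNA per pool was turned into biotin-labelled cDNA with the GeneChip WT kits.

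The deposited table holds 1 log2 value per probe set and array, called a probe here, and the submitters' processing notes name Affymetrix Expression Console 1.0, RMA and Partek 6.4 with no order or role. RMA corrects background, brings arrays to a common distribution and summarises several short oligonucleotides into 1 value per transcript on a log2 scale. The largest gap between the sorted log2 values of the deposited columns was 0.154. Which program wrote the values, its settings and the genome build are not given in the sources used here. RMA compresses differences of dim transcripts, and normalisation to a common distribution hides any change in total RNA per cell. The table carries no detection call, so background cannot be read from it, and the number of arrays limits the precision.

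Probes were named from the platform annotation. Of 28853 probes, 21789 had 1 gene symbol, 1621 had several and 5443 had none, and only those with 1 symbol were named. Of the probes with 1 symbol, 21698 matched the mouse reference gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols differed from it. That table was used for names and for the order of neighbouring genes, and none of its coordinates are printed. A gene was represented by its probe with the highest mean level, which gave 19938 genes, 999 of them with more than 1 probe.

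The difference is the log2 value of the knockout-labelled pool minus that of the wild-type pool, with no further scaling. Genes were kept when their mean level reached the 40th percentile of probes with 1 symbol, 5.44 on the log2 scale, which left 11924 genes. Counts were made at 1.5-fold and 2-fold in each direction. Each group holds 1 array, so there are no replicates, no p-value is given and pooling hides the spread between mice. The only repeat measurement is that of several probes for 1 gene. The SD between such probes was 0.143 on the log2 scale over 660 genes with 1809 probes, which covers probe error on these arrays and neither animals nor hybridisations.

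Gene lists, 39 in number with 938 symbols in all, covered liver metabolism, zonation, stress, inflammation, cell types and possible contaminants. Of these symbols 838 matched a measured gene. For each list the median difference of the members past the level filter is given with a 95% interval from the order statistics of its members, and with its percentile among 10000 random lists of the same size drawn from the same 10 level bins. A list of at least 5 members is said to stand apart when that percentile is below 2.5 or above 97.5. The percentile describes these arrays only. Genes of 1 pathway vary together, so it is more extreme than for unrelated genes. The 100 measured genes nearest to Fhl2 on its chromosome, 50 on each side, were summarised by their median absolute difference. Its percentile was taken among random lists and among 9728 windows of 100 neighbouring genes. These windows start at each successive gene along the autosomes, so they overlap, and they include the window around Fhl2.

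The lists, thresholds, alternatives and the rule for naming genes were set before the data were examined. The rule takes Fhl2, the 12 genes with the largest positive and the 12 with the largest negative difference past the filter, the 4 leading members of each list that stands apart, and members of any list past 2-fold, up to 3 per list and direction. Predicted gene models, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments are left out of the 12. Genes named outside this rule were chosen after their values were seen. Further gene sets for clock phase, feeding, glucocorticoid and growth hormone response, neutrophils and the secretory pathway serve the tests of explanations. Alternatives were a shift to a common median, removal of the trend on level by lowess with a span of 0.3, no level filter, a filter at the 60th percentile, the mean over a gene's probes, 20 level bins, lists without their most extreme member, list means, 25 genes on each side of Fhl2, and the share of neighbours past 1.5-fold.

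The steps were tested on simulated data made for the comparison of these pools over 11924 genes. Of 67 genes changed 1.5-fold, 61.2% passed 1.5-fold in the right direction, and of those changed 2-fold and 3-fold 100% did. Of 11724 unchanged genes 26 passed. The simulated noise was normal, with a spread per level bin taken from these same arrays. The 26 is therefore no false positive rate for the observed genes. Lists of 20 genes with no change were said to stand apart in 7% of 200 draws and lists shifted by 0.2 on the log2 scale in 96%. The window around Fhl2 lay at percentile 92.6 in a single draw without added differences and at 99.9 after its differences were widened 1.6 times. In 100 further draws without added differences, run after the observed percentile had been seen, its median percentile was 48.0 and 2 draws reached the observed one. These draws treat genes as independent. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.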

Results

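Gene expression in adult male liver was compared between a wild-type pool and a pool labelled as lacking Fhl2, a LIM-domain protein that binds transcription factors and signalling proteins. Each pool combined RNA of 3 mice and was hybridised to 1 array, so there are no replicates and every difference is between these pools. The medians of the arrays were 5.76 in the wild-type and 5.71 in the knockout-labelled pool on the log2 scale. Across all probes, which are not independent replicates, Pearson's r between the arrays was 0.995.

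Fhl2 itself was at 5.30 in the wild-type and 5.33 in the knockout-labelled pool, a difference of 0.02. It was represented by 1 probe, and its level lay at percentile 37.5 of the probes with 1 gene, below the level filter. The labels do not say which exons were deleted, so this probe neither supports nor contradicts the genotype, and the second pool is called the knockout-labelled pool throughout.

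The question set by the design is which liver transcripts differ without Fhl2. The transcripts highest in the knockout-labelled pool were Mfsd2a, a transporter of lysophospholipids, at 3.58-fold, Cabyr, a calcium-binding protein known from sperm, at about 3.34-fold over a dim wild-type value, and Lcn2, an iron-siderophore binding protein of the acute phase, at 3.12-fold. Alas1, the rate-limiting enzyme of heme synthesis, was 2.45-fold higher, and Onecut1, a liver-enriched homeobox transcription factor, was 2.41-fold higher. The lowest transcript was Bcl6, a transcriptional repressor, which was 3.94-fold lower, with 8.75 in the wild-type and 6.77 in the knockout-labelled pool. Creld2, a protein of the endoplasmic reticulum induced when folding is impaired, was 2.10-fold lower.

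Among 11924 genes past the level filter, 74 (0.621%) were at least 1.5-fold higher in the knockout-labelled pool and 40 (0.335%) at least 1.5-fold lower. Predicted models or small RNAs made up 3 of the higher and 3 of the lower genes. At 2-fold the counts were 11 higher and 2 lower. Higher genes were 64.9% of those past 1.5-fold, and 75% (90 against 30) when both arrays were shifted to a common median. Without the level filter they were 53.5% (153 against 133). Probes with no symbol or several symbols were counted with no level filter, which gave 65 higher and 109 lower at 1.5-fold. These do not add to the filtered counts. The genes kept lay close together, with 74.8% within 0.2 on the log2 scale and a median difference of 0.04. That median ran from -0.042 in bin 1 of 10 equal bins of rising level to 0.080 in bin 6.

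The other leading genes on the higher side have varied roles. Zfp42, a zinc finger protein of pluripotent cells, was 2.36-fold higher, Meg3, an imprinted noncoding RNA, 2.26-fold, and Saa2, a serum amyloid A apolipoprotein, 2.25-fold. Ppp1r10, a nuclear regulator of a protein phosphatase, was 2.19-fold higher, Inhbe, an activin subunit secreted by liver, 2.17-fold, Cyp26a1, which degrades retinoic acid, 2.14-fold, and Orm3, an orosomucoid, 1.91-fold. Cabyr, Zfp42 and Orm3 lay below the filter level of 5.44 in the wild-type pool, at 4.84, 4.87 and 5.41, so the size of their folds is uncertain.

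S1pr2 and S1pr4, both receptors for sphingosine phosphate, were 1.93-fold and 1.84-fold lower. No gene list covered this receptor family, so a family pattern was not tested. The histone gene H2bc9 was 1.92-fold lower, the zinc importer Slc39a10 1.83-fold, the ribosomal protein retrogene Rpl10l 1.82-fold, and Asns, which makes asparagine, 1.81-fold. Depp1, a regulator of autophagy under FOXO control, was 1.71-fold lower, the membrane protein gene Smim3 1.67-fold, the nucleic acid binding protein gene Purg 1.64-fold, and the transferrin receptor Tfrc 1.64-fold. In the knockout-labelled pool S1pr4, Purg and Slc39a10 lay below 5.44, at 5.10, 5.33 and 5.39, so their folds are uncertain in size too. Serum amyloid, orosomucoid and histone genes belong to families of near-identical members whose transcripts can share probes, so the value of 1 member is uncertain.

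**Figure D1:**
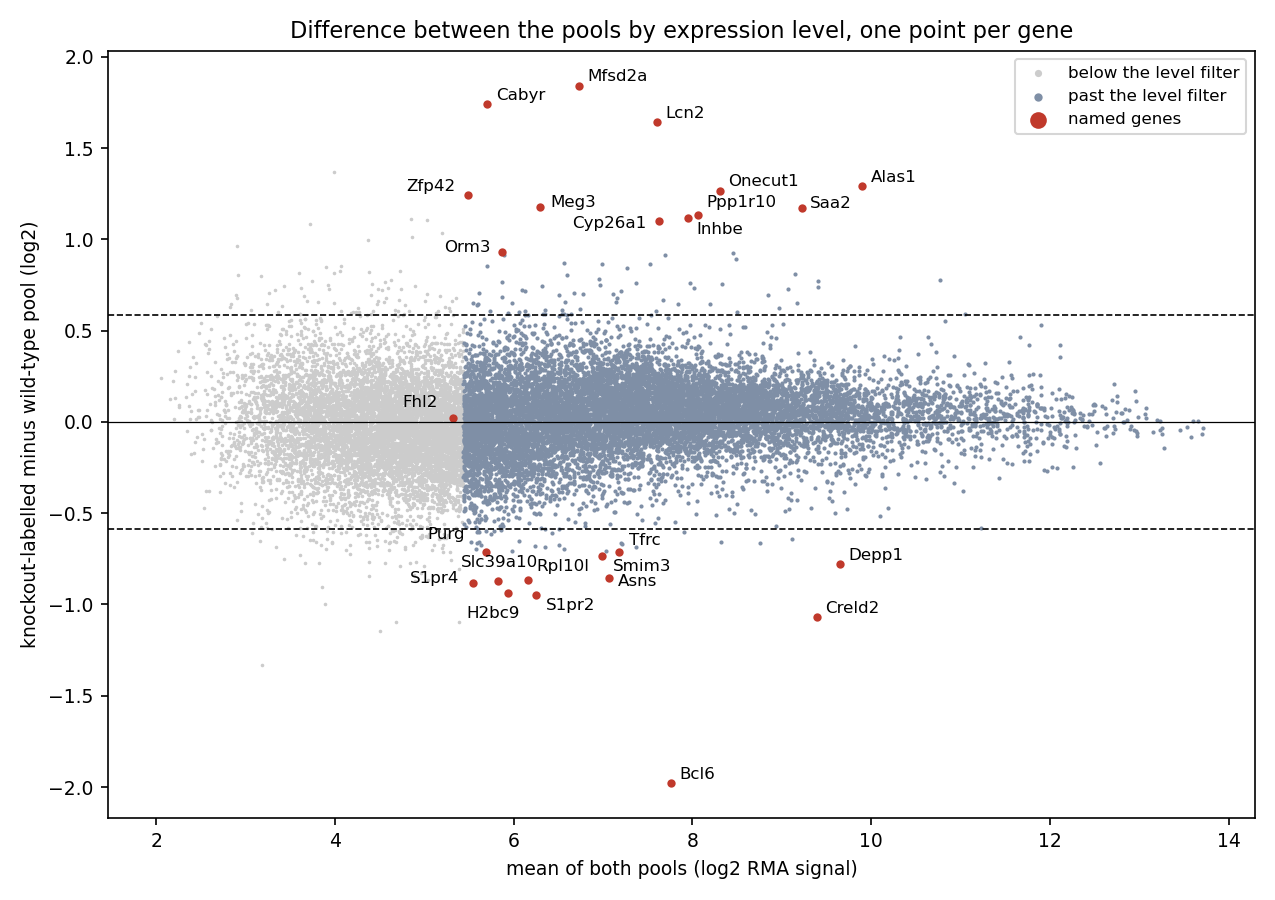
Difference between the pools (knockout-labelled minus wild-type, log2) against the mean log2 level of both pools, 1 point per gene, with the genes below the level filter in light grey, Fhl2 and the 12 genes at each end in red, and dashed lines at 1.5-fold. Bcl6 lies lowest at -1.98 and Mfsd2a highest at 1.84, while Fhl2 lies at 0.02.

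Gene lists asked which pathways and cell types differed as groups. Of 35 lists with at least 5 members, 15 stood apart from random lists of the same level. They were 5 on the higher and 10 on the lower side. If all genes were unrelated, 1.75 lists would stand apart by chance. Genes of a pathway vary together and some lists share members, so more than 1.75 can stand apart under any difference between these pools. The excess of 15 over 1.75 was therefore not tested. Cholesterol synthesis and acute phase genes were among the higher lists, and endoplasmic reticulum stress, heat shock, ribosomal protein and macrophage genes among the lower ones. These 6 lists and the bile acid list make up the 7 that stood apart under all 7 alternatives able to move a list's percentile, which a shift to a common median is not.

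Cholesterol biosynthesis genes, targets of the sterol regulator SREBP2, had a median difference of 0.19 (95% interval over 20 members 0.06 to 0.24), above all 10000 random lists. Of the 20 genes, 17 were above 0 and 0 reached 1.5-fold. Leading members were Idi1, an isoprenoid isomerase (0.42), Hmgcs1, which makes the precursor of mevalonate (0.34), the cyclase Lss (0.28) and the sterol dehydrogenase Nsdhl (0.27). Fatty acid and triglyceride synthesis genes had a median of 0.07 and percentile 87.5, with 1 member past 1.5-fold, Elovl6 (0.64, chosen after its value was seen).

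Bile acid synthesis and transport genes had a median of 0.11 (0.03 to 0.19, 21 members, percentile 99.1), and 16 of the 21 were above 0. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.53, the sterol exporters Abcg5 and Abcg8 both at 0.30, and the racemase Amacr at 0.21. Drug metabolism genes, targets of the nuclear receptors CAR and PXR, had a median of 0.14 (0.02 to 0.19, 17 members, percentile 99.9). Cyp2b10 was 1.58-fold higher as the 1 member past 1.5-fold, with the sulfotransferase Sult1d1 at 0.31, the receptor PXR gene Nr1i2 at 0.23 and the glutathione transferase Gstt1 at 0.22. Wnt and pericentral genes, active around the central vein, had a median of 0.14 (0.04 to 0.26, percentile 99.6), with 16 of 18 above 0. The aminotransferase Oat was at 0.42, the ammonium transporter Rhbg at 0.35 and the glutamate transporter Slc1a2 at 0.28. Glutamine synthetase Glul was at 0.33, or 0.185 with the mean over its 2 probes. Periportal genes, from the opposite end of the lobule, had a median of 0.03 and percentile 40.5.

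Acute phase genes, many of which encode proteins that liver secretes in inflammation, had a median of 0.12 (0.03 to 0.34, 25 members, percentile 99.7). At least 1.5-fold higher were 5 of the 25, namely Lcn2, Saa2, Orm3, Saa1 at 1.90-fold and Orm2 at 1.75-fold, and 0 were as much lower. The fibrinogen genes, also of this list, were at 0.08 for Fga, -0.03 for Fgb and -0.06 for Fgg. Inflammatory genes under NF-kappaB lay on the other side, with a median of -0.10 (-0.20 to 0.25, 14 members, percentile 1.80), which turned to 0.03 with the level filter at the 60th percentile. This list no longer stood apart under 5 of these 7 alternatives. Among its members the apoptosis inhibitor Birc3 was at -0.44, the endotoxin co-receptor Cd14 at -0.41, the chemokine Ccl5 at -0.20 and the adhesion molecule Icam1 at -0.18. Interferon-stimulated genes were at -0.01 (percentile 8.98), or 0.03 after the common median shift, and complement and coagulation genes at 0.08 (percentile 94.1), or 0.12 after that shift.

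Endoplasmic reticulum stress genes, which respond to impaired protein folding, had a median of -0.25 (-0.42 to 0.01, 25 members), below all 10000 random lists. Of the 25, 3 were at least 1.5-fold lower, namely Creld2, Asns and the chaperone cofactor Sdf2l1 at 1.58-fold. The chaperone Hspa5 was at -0.58, while 8 members were above 0, among them the transcription factor Atf4 at 0.46. Heat shock genes had a median of -0.11 (-0.30 to 0.01, 18 members, below all random lists), or -0.07 after the common median shift, with the chaperones Hsph1 at -0.41, Hspb1 at -0.40 and Hsp90aa1 at -0.31 and the co-chaperone Stip1 at -0.34. Ribosomal protein genes had a median of -0.05 (-0.09 to -0.0028, 40 members, below all random lists), which was -0.013 after the common median shift and -0.02 as a mean. Rpl29 was at -0.30, Rpl7a at -0.22, Rps4x at -0.16 and Rps15 at -0.16. With the mean over a gene's probes Rpl7a and Rps15 were both at -0.10 and Rps4x at -0.20. Proteasome genes had a median of -0.013 (-0.03 to 0.02, 31 members, percentile 1.87), which turned to 0.03 after the common median shift, with Psmc2 at -0.12, Psma1 at -0.09, Psma6 at -0.06 and Psma3 at -0.05. Oxidative phosphorylation genes had a median of 0.02 (percentile 22.1) over 46 members, or 0.06 after the common median shift.

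Kupffer cell and macrophage markers had a median of -0.16 (-0.28 to -0.0077, 20 members, below all random lists), and 4 of the 20 were above 0. The receptors Adgre1 and Marco were at -0.40 and -0.38, lysozyme Lyz2 at -0.36 and the actin-binding protein Aif1 at -0.36. The list of B and plasma cell markers had 6 members past the filter and a median of -0.30 (-0.48 to 0.14, below all random lists). Without the level filter, which had left out 12 members, the median was -0.09 and the list no longer stood apart. Its leading members present antigen on MHC class II, which macrophages also do, with H2-Ab1 at -0.48, H2-Aa at -0.40, H2-Eb1 at -0.31 and Cd74 at -0.28. Sinusoidal endothelial markers had a median of 0.12 (percentile 96.8, 23 members), or 0.16 after the common median shift, and hepatocyte identity genes a median of 0.01 (percentile 15, 24 members). T and NK cell markers were at -0.15 (percentile 9.27, 7 members) and bile duct markers at 0.07 (percentile 80.4, 8 members), or -0.01 with the mean over a gene's probes.

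Extracellular matrix and stellate cell genes had a median of -0.04 (-0.09 to 0.09, 29 members, percentile 1.69), which became 0.0011 after the common median shift. The collagens Col1a1 at -0.37, Col4a2 at -0.29, Col4a1 at -0.25 and Col6a1 at -0.23 led it. Male-biased liver genes had a median of -0.06 (-0.11 to 0.08, 17 members, percentile 0.25), or -0.02 after the common median shift, with the glucuronosyltransferase Ugt2b38 at -0.38, the elongase Elovl3 at -0.27, the urinary protein Mup3 at -0.22 and the oxysterol hydroxylase Cyp7b1 at -0.19. Female-biased genes had a median of -0.15 (-0.43 to 0.09, 9 members, percentile 0.37), with 4 of the 9 above 0, and it turned to 0.03 without the level filter, which had left out 10 members. The peroxisomal transporter Abcd2 was 1.62-fold lower, and the cytochromes Cyp3a44, Cyp2c39 and Cyp4a14 were at -0.43, -0.23 and -0.19. Cyp17a1, another member, was at 0.80.

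The remaining lists did not stand apart as set, and 4 lists did under an alternative. These were circadian clock genes (0.13) and bile duct markers (0.12) without the level filter, and gluconeogenesis and FOXO1 targets (-0.05) and fatty acid oxidation genes (0.15) as means. Related LIM-domain genes had a median of -0.0057 (percentile 17.3), or 0.04 after the common median shift and 0.03 with the mean over a gene's probes. Serum response factor targets were at 0.04 (percentile 48.4), immediate-early and AP-1 genes at 0.07 (percentile 69.0), p53 targets at 0.07 (percentile 71.4) and cell cycle genes at 0.05 (percentile 78.6). The immediate-early list turned to -0.0012 without the level filter. Gluconeogenesis and FOXO1 targets were at 0.04 (percentile 38.0), with 9 of 18 above 0. They include Bcl6 at -1.98, which weighs on their mean of -0.05, and the mean without Bcl6 was not taken. Fatty acid oxidation genes were at 0.08 (percentile 86.5), with Acot4 (0.87), Acot2 (0.75) and Angptl4 (0.64) past 1.5-fold and named after their values were seen. NRF2 targets were at 0.06 (percentile 74.2) and circadian clock genes at 0.06 (percentile 68.6), or -0.0060 for the clock list with the mean over a gene's probes. Skeletal muscle and fat cell markers were at -0.11 (percentile 13.8) and -0.06 (percentile 11.3). Neutrophil, red blood cell, exocrine pancreas and sex chromosome lists had 3, 4, 4 and 3 members past the filter, too few to place.

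The other 8 lists that stood apart were lost under at least 1 alternative: Wnt, drug metabolism, male-biased, female-biased, NF-kappaB, matrix, proteasome and B cell.

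**Figure D2:**
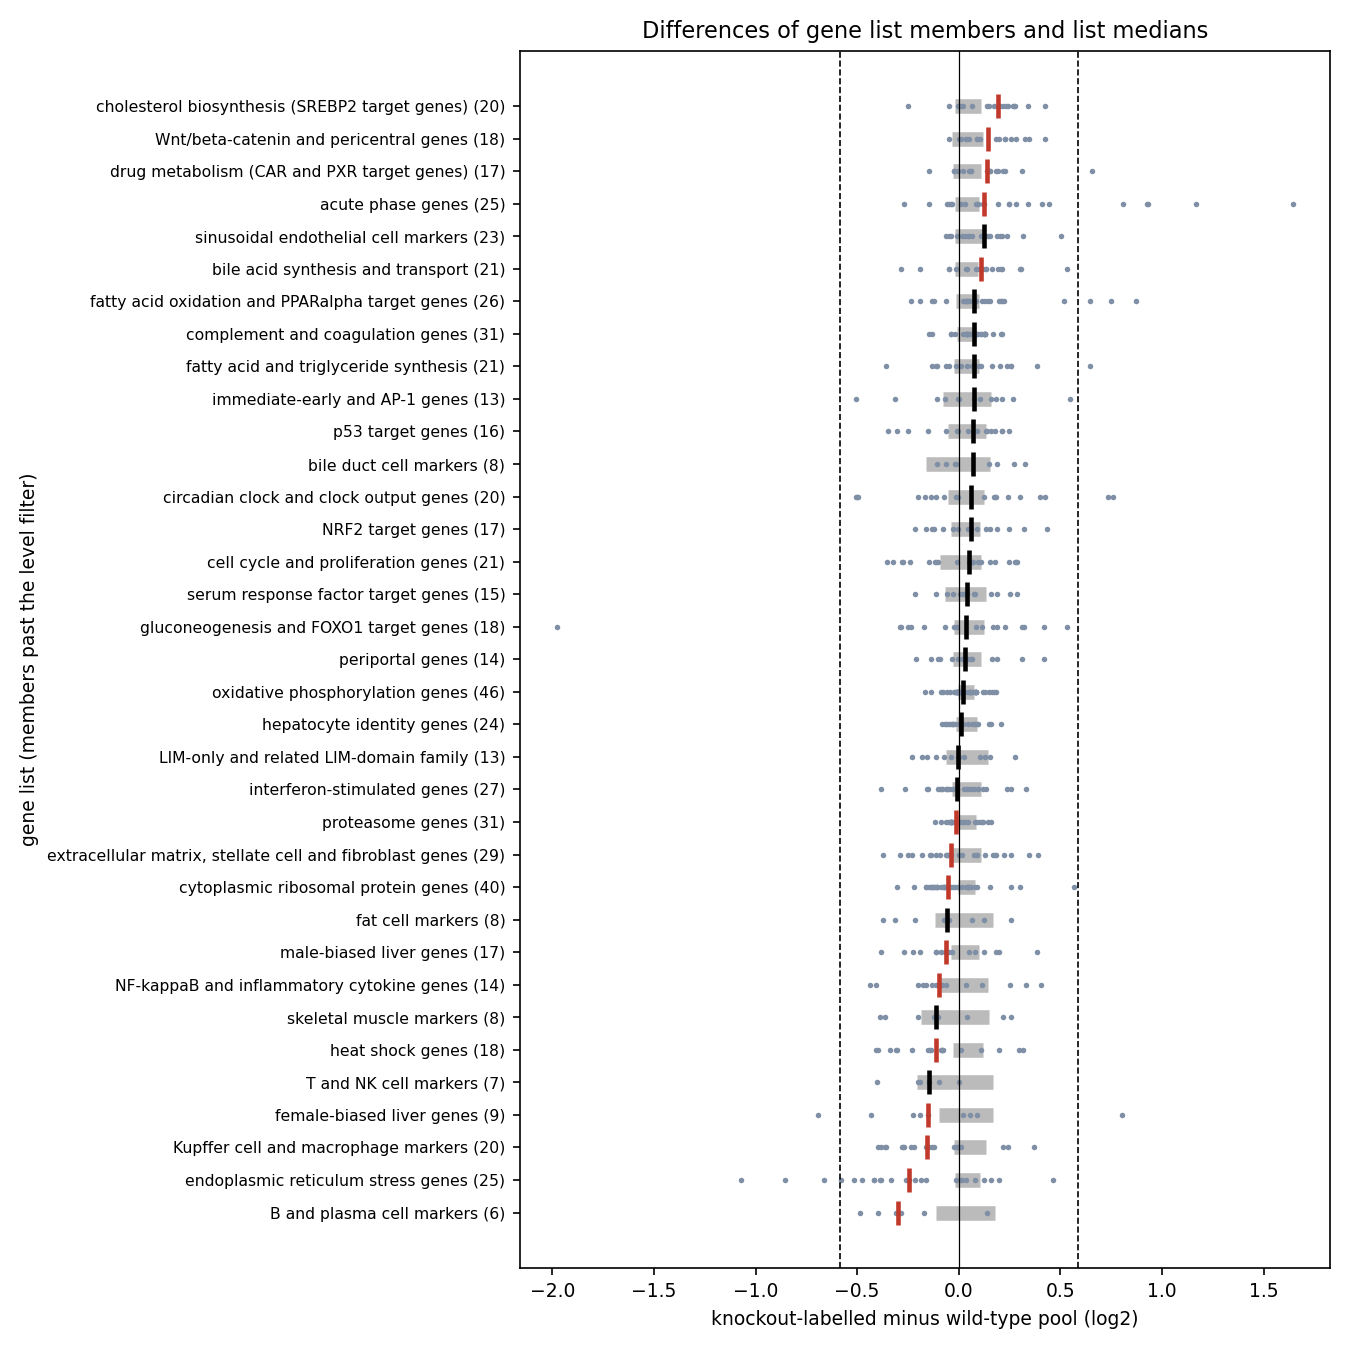
Differences (knockout-labelled minus wild-type, log2) of the members of 35 gene lists as points, with the list median as a vertical tick, red where the list stood apart, the middle 95% of random level-matched list medians as a grey bar, and dashed lines at 1.5-fold. The cholesterol list has the highest median at 0.19 and the B and plasma cell list, with 6 members, the lowest at -0.30 (-0.09 without the level filter), while the matrix and proteasome medians turn positive under a common median shift.

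Genes beside Fhl2 on its chromosome were examined because a targeted allele is carried with flanking chromosome of its donor strain and these mice had a mixed background. The 100 nearest measured genes had a median absolute difference of 0.145 (95% interval over genes 0.110 to 0.182), against 0.115 for all genes. This lay at percentile 98.2 of random lists and percentile 98.0 of the windows of neighbouring genes. The windows overlap and include those around Fhl2, so they are not an independent reference. At least 1.5-fold apart were 2 of the 100 (2.0%, against 0.956% of all genes), namely Slc39a10, 12 genes away, and Ormdl1, a regulator of sphingolipid synthesis 21 genes away, which was 1.88-fold higher. Ormdl1 and the adaptor gene Nck2, next to Fhl2 at 0.42, were chosen after their values were seen. Without the level filter the percentile among random lists was 87.7, and for the share of genes past 1.5-fold it was 83.8. With 25 genes on each side it was 98.1.

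**Figure D3:**
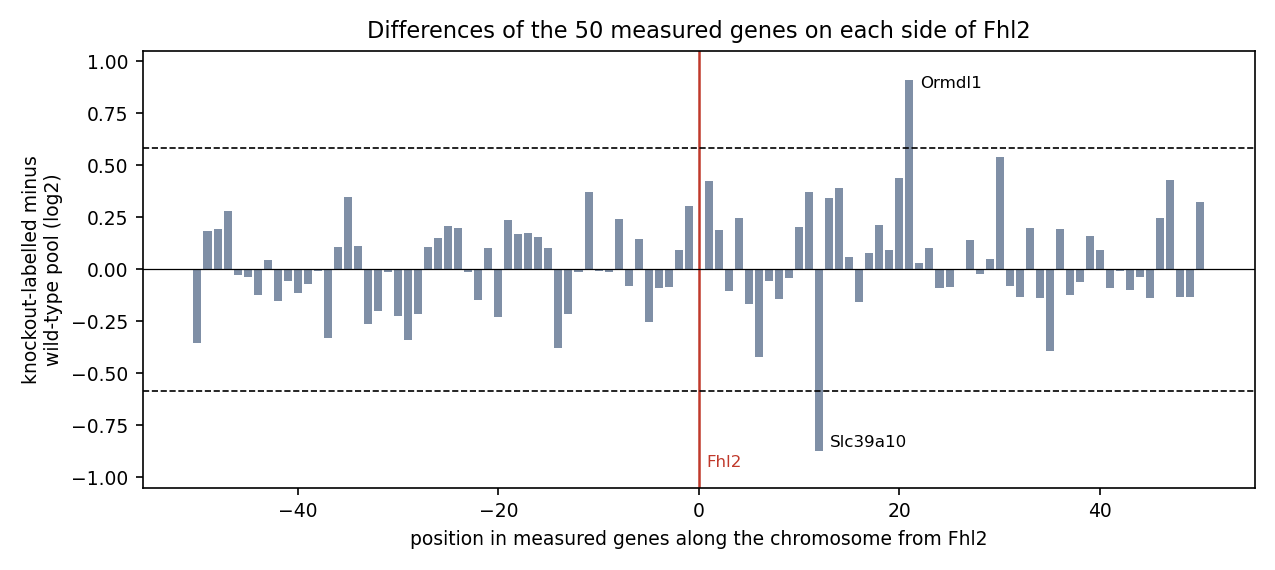
Difference (knockout-labelled minus wild-type, log2) of each of the 50 measured genes on either side of Fhl2, as bars in chromosome order, with dashed lines at 1.5-fold. Ormdl1 at 0.91 and Slc39a10 at -0.87 pass the lines.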

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

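Added after the data were seen were the sets without genes already looked at, the mean for the stress list's trend test and the minimum of 6 members for the growth hormone and neutrophil tests. All 80 named genes moved by less than the 0.143 SD between probes under the shift to a common median, lowess and the mean of probes. A level filter cannot move the value of a single gene. The mean of probes cannot move a gene with 1 probe, as most named genes had. Under that mean Glul moved from 0.327 to 0.185 and Rpl7a from -0.22 to -0.10. Without the level filter, 153 genes were at least 1.5-fold higher and 133 lower, and 17 and 6 at 2-fold. With the filter at the 60th percentile there were 41 higher and 14 lower at 1.5-fold, since fewer genes are counted. Of the 114 genes past 1.5-fold, 104 remained after the common median shift, 100 after lowess and 111 with the mean of probes. The shift moves every gene by the same amount.

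Between 11 and 15 lists stood apart under the alternatives. The matrix list turned to 0.0011 and the proteasome list to 0.028 after the common median shift, and to 0.0013 and 0.0085 as means. The female-biased list turned to 0.027 without the filter and the NF-kappaB list to 0.033 at the 60th percentile. The percentile of the genes around Fhl2 dropped to 87.7 without the filter and to 83.8 for the share past 1.5-fold, and was 98.1 with 25 genes on each side. Except where a filter sets which genes are counted, or where the shift adds the same amount to every gene, the cause was not tested. No paired analysis was possible because each group holds 1 array. The log2(value + 16) alternative was not run because the values already were logarithms. Low signals limit the dim genes most, with an SD of 0.229 in the lowest of 10 level bins and 0.136 in the highest.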

Other observations

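Chosen after the result was seen were the neutrophil test and the rule that decides it, the 100 simulated draws for the genes around Fhl2, the mean that decides the trend test, the minimum of 6 members for the growth hormone test, and the sets without Dbp, without acute phase members and Angptl4, and without the leading stress genes.

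Of 10 clock genes that peak toward evening, 8 were above 0 in the knockout-labelled pool, and of 4 that peak toward morning 0 were. Both sets come from the clock list and leave out some of its members. That whole list had 20 members past the filter, 10 of them above 0, and percentile 68.6. The evening genes had a median difference of 0.18, with the clock output regulator Dbp at 0.76, the repressor Per1 at 0.43, Ciart at 0.40 and Nr1d1 at 0.24, against Usp2 at -0.20 and Hlf at -0.11. The morning genes had a median of -0.32, with the activator Arntl at -0.51, the repressors Cry1 at -0.50 and Nfil3 at -0.14, and Clock at -0.07. The contrast of 0.50 lay above all 10000 random contrasts and was 0.49 without Dbp. Time of day at dissection was weighed only for the stress list below, so its part in the other genes and lists was not tested.

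Glucocorticoid target genes had a median of 0.34 (0.12 to 0.42, 16 members), and 15 of the 16 were above 0. Fkbp5, a cochaperone of the receptor, was at 0.34, the zinc finger gene Zbtb16 at 0.34, the stress gene Ddit4 at 0.42 and the leucine zipper gene Tsc22d3 at 0.21. Secretory pathway genes outside the stress list, which move proteins into and through the endoplasmic reticulum, had a median of -0.08 (-0.13 to -0.04, 43 members), and 7 of the 43 were above 0. The translocon-associated protein Ssr1 was at -0.32 and the signal recognition particle subunit Srp68 at -0.28.

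Endoplasmic reticulum stress genes were lower, and without Creld2, Asns, Sdf2l1 and Hspa5 the median was -0.19 (-0.38 to 0.03, percentile 0, 21 members, 8 above 0), with an interval that reached past the random bound of -0.03. The trend of the difference on level is argued against as the whole cause. Its planned removal left the median at -0.22, from -0.25, and the medians of the level bins ran only from -0.042 to 0.080. The percentile stayed at 0, but its random lists were already matched on level, so the removal could hardly change it. The interval of the corrected median, -0.43 to -0.0020, did reach past the random bound of -0.03, and by the rule first used that left the trend open. The mean, taken after that outcome, was -0.25 (-0.39 to -0.12) against a random bound of -0.03. Time of day at dissection, with the clock contrast at percentile 100, may go with the pattern. Secretory pathway genes were lower too, at percentile 0, which widens the pattern and tests no separate cause. Feeding state stays open at percentile 87.4. The genotype, which the design confounds with all of these, was not tested apart from them.

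Acute phase genes were higher. Neutrophils or blood left in the rinsed livers stay open. The 15 neutrophil markers other than Lcn2 and Il1b had a median of -0.115 (-0.31 to 0.07), but 14 of them lay below the level filter. The rule first used, a median at or below 0 with 4 markers dimmer than Lcn2, argued against neutrophils, and the rule that leaves them open was set after that outcome. Glucocorticoid exposure is a candidate explanation, at percentile 100 for its targets and also for the 13 targets outside the acute phase list and Angptl4. Handling, time of day and genotype cannot be separated with 1 pool per group.

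Genes around Fhl2 differed more than most windows. A donor-strain segment is a candidate explanation, with percentile 98.0 among windows, which overlap and include those around Fhl2. But the median of 0.145 was close to the window bound of 0.142. Without the level filter the percentile among level-matched lists was 87.7. Of 100 simulated draws without added differences, which treat genes as independent, 2 reached the observed percentile. That number follows from the percentile itself, so it adds no support for a segment. Probe level stays open, because the percentile among level-matched lists was 98.2 but the interval of 0.110 to 0.182 includes the random bound of 0.143.

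Lower Bcl6 with higher Onecut1 led to the hypothesis of a growth hormone pulse, which could raise targets of STAT5. Cish, Socs2, Socs3, Igf1 and Igfals had a median of 0.16 and percentile 92.5, short of the upper bound set for it. Resampling of the 5 members gave an upper end of 0.201, just under the random bound of 0.207, which by the rule first used argues against the hypothesis. A minimum of 6 members, added after that value was seen because fewer give no 95% interval, leaves it open.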
